A study of Escherichia coli and Caulobacter vibrioides NA1000 with 27 samples.

How the data were processed

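FLAG ChIP-seq was analysed in 27 libraries, 9 from Caulobacter crescentus NA1000 strain MT148 and 18 from Escherichia coli AB1157 with parS inserted at ygcE. Per the labels' protocols, C. crescentus was grown in 25 mL of PYE medium in the presence of vanillate at 0.5 mM and glucose at 0.3%. E. coli was grown in 25 mL of LB at 28 °C, and 1 mM IPTG was added for 1 to 3 h, a time picked so that an anti-FLAG immunoblot showed similar protein levels. Cells were fixed with 1% formaldehyde at, or after induction from, an OD600 of 0.4, and libraries were made with the NEBNext Ultra II kit. Samples were placed in groups by the titles in the labels, which gave 19 groups. The titles name the E. coli strain TLE3002 and the genotype field TLE3200, and both were taken to mean the same strain.

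The deposited files hold coverage, the number of mapped reads over each base, in 1 file per library with no scaling for depth. Bowtie and bedtools are named in the submitters' processing notes, while their versions and settings, the treatment of duplicate reads and that of reads with several matches are not given in the sources used here. Each file was checked to be an exact sum of 51-bp reads, which gave the number of reads per library, 1708889 to 13842301 in C. crescentus (mean coverage 21.6 to 175) and 2129474 to 8292141 in E. coli (23.4 to 91.1). Since 51 bp were laid at each read start and not the whole fragment, peaks are narrower and more shifted than with extended fragments. Bases with no read made up 1.18 to 1.20% of the C. crescentus sequence and 2.99 to 3.06% of the E. coli sequence. Genes with near-identical copies, such as those of ribosomal and transfer RNA, therefore have uncertain values. The E. coli files use the K-12 MG1655 reference (ASM584v2), for which gene names and positions were taken from the RefSeq gene table. The C. crescentus files use a sequence named CB15N, and no gene names are printed for it because an annotation of it was not used here. No genome sequence was used, so matches to the parS motif were not analysed here.

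From the coverage, each library was scaled to its background, the median per-base coverage outside 100 kb of the parS centre. The centre of each organism was the highest 101-bp running mean of the equal-weight mean profile, over the 8 ParB libraries in C. crescentus and over the 18 libraries in E. coli. In E. coli, coverage near the centre fell to its lowest at 2903376, 239 bp from the centre, which was taken as the junction of the inserted site. Reads across an insertion would have no match in the reference, but this was not checked, since no sequence of the insert was used. The core fold (within 250 bp), the flank fold (1 to 10 kb on both sides), the distal share and the domain width were computed per library. The width counts 500-bp bins at or above 2 times background, and a side ends at the first 2 consecutive bins below. Background was scaled per library, so a fold compares occupancy within a library with its own surroundings and not absolute amounts of DNA.

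Differences among the 4 ParB groups of C. crescentus and among the 4 chimeras were tested with a two-sided exact permutation test over every way of parting 8 libraries into 4 pairs. Its statistic was the sum of squares between groups of the log2 values (with 0.5 kb added to the width), or of the plain distal share, and Benjamini-Hochberg adjustment covered all 8 such tests. The smallest p this test can give is 0.00952. Bins of 1 kb were tested with limma 3.58.1 in R 4.3.3 on log2(fold + 0.1), with an intensity trend and Benjamini-Hochberg adjustment at 0.05, over bins with a mean fold of 0.2 or more. Because of the added 0.1, log2 fold changes understate the change of low bins. The fit for C. crescentus held all 9 libraries, and that for the chimeras held the 8 chimera libraries and the single C. crescentus ParB library of E. coli. The 10 single ParB libraries of E. coli were compared by their values only. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with figures from matplotlib 3.10.9.

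Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 3.12 to 12.0 over 1-kb bins, so none was treated as 1 library. The correlation of log2 coverage in 500-bp bins was 0.937 to 0.988. Replicate numbers come from the titles. Deviations from the group means of libraries with the same number correlated at 0.144 to 0.582 in all 6 pairs of C. crescentus groups, so these numbers were taken as pairs there. The pairs with wild type had only 0.144 to 0.208, so a pairing of wild type with the variants is not established. Depth follows the number too, since the second replicates of 3K, 4K and 5K are the 3 deepest libraries. In E. coli the 6 correlations ran from -0.0817 to 0.262, so the numbers were not taken as pairs, although depth follows the number there too. Binomial intervals of read shares are exact 95% Clopper-Pearson intervals. They cover counting error only, since reads were not tied to molecules by identifiers.

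The tests, the alternatives and the rule for named regions were set before the data were examined. Named regions are the centre, the outermost gene on each side at 2 times background, and per limma comparison the 10 bins with the largest increase and the 10 with the largest decrease among those called with groups that do not overlap, adjacent bins merged. They also include up to 10 other peaks per group, which are 500-bp bins beyond 50 kb of the centre at 3 times background or more in each library of a group, with YFP or the median of the 10 single libraries below 1.5. Members of fixed gene lists at 2 times background or more, or at 0.5 times or less, complete the rule. Of the other peaks and the list members, the few that lead are named and the rest are given as counts. The lists were segregation and chromosome organisation genes, origin-proximal genes, ribosomal protein genes, tRNA genes, rRNA genes, the lac genes, genes reported as lost in relatives of AB1157 and the neighbours of the inserted site. The median fold of each list was placed among 10000 random lists of the same size and, added after seeing the data, among 10000 lists matched on position, with each member replaced by a gene within 200 kb. Lists for C. crescentus were not analysed here. The summits, the plateau, the dip, the ends of the domains and the block at lacZ and lacI were chosen after the profiles had been seen, and so was wild type against all variant libraries.

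The alternatives were another background (the mean, or the local flanks 50 to 100 kb away), other windows (500 bp for the core, 0.5 to 5 kb and 2 to 20 kb for the flanks), thresholds of 1.5 and 3 times for the width, and 2 and 5 times for other peaks. For bins they were sizes of 0.5 and 2 kb, pseudocounts of 0.02 and 0.5, no filter, mean scaling, quantile normalisation, the replicate number as a block and leaving out each replicate. Added after seeing the data were thinning of reads to the shallowest library of the organism, the junction as centre, leaving out the 3 deep libraries of C. crescentus, the replicate block with thinned reads and the block for wild type against all variant libraries, in which 1 library of each number is taken as wild type.

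The limma step was tested on simulated data. For 3K against wild type, 100% of the 100 bins changed 2-fold and of the 100 changed 4-fold were recovered, and 16 of 216 calls over 4015 bins (7.41%) were false. For chimera B against A, 100% of 100 and of 98 bins were recovered, and 6 of 204 calls over 4531 bins (2.94%) were false. The simulated replicates varied less than the real ones, so the recovery is optimistic.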

Results

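ParB is the DNA-binding protein of the ParABS chromosome segregation system. It binds centromere-like parS sites and occupies the DNA around them. FLAG-tagged ParB was mapped by chromatin immunoprecipitation with an anti-FLAG antibody followed by sequencing (ChIP-seq), in 27 libraries from 2 bacteria. In Caulobacter crescentus NA1000, 9 libraries came from strain MT148, in which parB is placed behind the Pxyl promoter and a FLAG-tagged protein is made from the Pvan promoter at vanA. They comprised 2 libraries each of wild-type ParB and of the variants named 3K, 4K and 5K, and 1 library of FLAG-tagged YFP, a fluorescent protein used as the background control. In Escherichia coli AB1157, a laboratory K-12 strain carrying parS inserted at ygcE, 18 libraries came from cells making FLAG-ParB from plasmid pUT18C. They comprised 1 library for each of 10 ParB proteins from different species and 2 libraries for each of the 4 ParB chimeras A to D. What the 3K, 4K and 5K changes and the 4 chimeras consist of is not given in the sources used here.

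Depth ran from 1708889 to 13842301 mapped reads per library in C. crescentus and from 2129474 to 8292141 in E. coli. Per replicate, wild-type C. crescentus ParB had 1708889 and 4030088 reads, 3K had 2595816 and 13842301, 4K had 2170814 and 13218189, 5K had 2557752 and 11197735, and YFP had 4041786. In E. coli the 10 single libraries had 2129474 to 2987355 reads, and the first and second replicates of the chimeras had 2932118 and 7188211 for A, 3035221 and 6822771 for B, 2852261 and 7382346 for C, and 2409626 and 8292141 for D. All values below are folds over the library background, the median per-base coverage outside 100 kb of the parS centre. The core fold is the mean within 250 bp of the centre, and the flank fold the mean from 1 to 10 kb on both sides. The distal share is the percent of the coverage above background within 10 kb that lies beyond 1 kb. The domain width is the contiguous length at or above 2 times background. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

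The first comparison asked how the ParB variants differed at the native parS region of C. crescentus. On the sequence the submitters named CB15N, the 8 ParB libraries peaked at position 4034924, where the single YFP library had a core fold of 1.23 and a flank fold of 1.18. Wild-type ParB had a core fold of 56.0 ± 15.5 (SD, n = 2), against 21.7 ± 1.37 for 3K, 24.4 ± 10.3 for 4K and 21.7 ± 14.4 for 5K (SD, n = 2 each). The flank fold was 6.80 ± 1.02 for wild type, 3.16 ± 0.333 for 3K, 3.30 ± 0.936 for 4K and 3.01 ± 1.31 for 5K. The domain measured 10.5 kb in both wild-type libraries, 9.25 ± 0.354 kb in 3K, 8.75 ± 0.354 kb in 4K and 8.75 ± 0.354 kb in 5K. In the group means it ran from 4030424 to 4040923 in wild type and from 4030924 to 4039923 in each variant. The distal share differed little, at 59.9% ± 1.41 for wild type, 60.7% ± 1.01 for 3K, 59.6% ± 1.01 for 4K and 59.9% ± 2.58 for 5K.

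**Figure D1:**
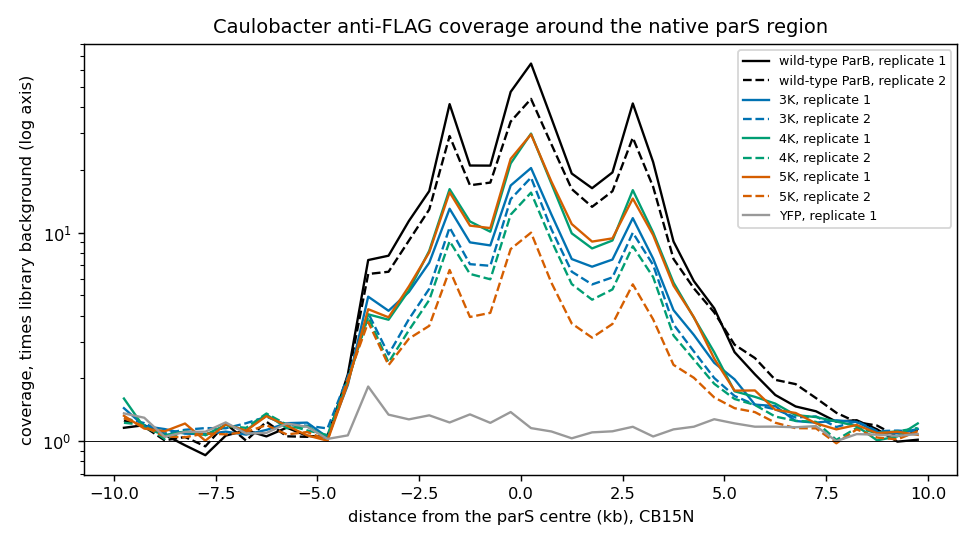
Fold over background (log axis) against position around the parS centre of C. crescentus in 500-bp bins, 1 line per library of wild-type, 3K, 4K and 5K ParB and of YFP. The 2 wild-type libraries lie highest around the centre, with core folds of 67.0 and 45.1. YFP stays close to 1 except near the block from 4031044 to 4031392, where its mean fold is 2.07.

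Across the 4 groups none of these differences passed the test against the spread between replicates. The two-sided exact permutation test over every way of parting the 8 libraries into 4 pairs gave p = 0.238 for the core fold, 0.133 for the flank fold, 0.886 for the distal share and 0.0857 for the domain width. Benjamini-Hochberg adjustment over the 8 such tests of both organisms gave 0.272, 0.178, 0.886 and 0.137. With reads thinned to the shallowest library, a step chosen after seeing the data, the exact permutation p for the width was 0.0286, and 0.0833 with the replicate number as a block. When the pair of wild-type libraries was instead set against the 6 variant libraries, a comparison chosen after seeing the data, wild type was higher in core fold, flank fold and width. Both wild-type libraries exceeded all 6 variant libraries in each of the 3 quantities, with exact permutation p = 0.0357, the smallest that the 28 splits allow, and 0.0476 after Benjamini-Hochberg adjustment over these 4 tests, while the distal share gave p = 0.821. The replicate numbers were taken as pairs, and with the number as a block the exact permutation p was 0.0625 for each of the 3. That is the smallest that the 16 assignments allow, so the block could not call any of them. The mean core fold was 2.48 times that of the variants and the mean flank fold 2.15 times. Without the library labelled 5K replicate 2, which had the lowest core fold of the 8 at 11.6, these ratios were 2.26 and 2.02. The second replicates of 3K, 4K and 5K were sequenced far more deeply than the rest. Among the libraries of mean coverage under 100, the ratios were 1.95 and 1.81, and 2 libraries against 3 reached the smallest exact permutation p that they can, 0.1.

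The domain held 5 local summits between 4031346 and 4037789, whose positions were read from the mean profile. Both summits beside the centre stood lower against the centre in the variants than in wild type. At 4033206 the fold was 46.9 in wild type and 15.2 over the 6 variant libraries, and at 4037789 it was 48.0 and 15.1, ratios of 3.10 and 3.18, against 75.0 and 32.8 at the centre, a ratio of 2.29 (exact permutation p = 0.0357 for each fold, adjusted p = 0.0429 over 6 positions, and 0.0625 with the replicate block). As a percent of the excess at the centre, the summit at 4033206 measured 62.3% ± 1.19 in wild type (SD, n = 2) and 44.9% ± 2.29 in the variants (SD, n = 6). The summit at 4037789 measured 63.9% ± 2.76 and 43.9% ± 3.37. Wild type and variants did not overlap at 4033206 (61.41 to 63.09% against 42.54 to 48.78%) or at 4037789 (61.95 to 65.85% against 38.09 to 47.03%). The exact permutation p was 0.0357 for each, the smallest that the 28 splits allow. After Benjamini-Hochberg adjustment over 5 summits it was 0.0893, so neither passed the correction. With the block the exact permutation p was 0.0625 for each. That is the smallest that the 16 assignments allow, so the block cannot decide. The summit at 4031346 lies in a block that is raised in YFP as well, where YFP had 1.91. The outer summits at 4032163 and 4031346 measured 17.4% and 11.1% of the centre in wild type and 14.8% and 13.6% in the variants (exact permutation p = 0.107 and 0.429). A remote site at 3764141 had a fold of 7.41 in wild type, 5.37 in the variants and 1.16 in YFP, and wild type and variants did not differ there by more than the spread (exact permutation p = 0.286). As a percent of the centre excess it measured 8.40% ± 1.47 in wild type and 14.0% ± 3.28 in the variants (exact permutation p = 0.0714, and 0.0625 with the block). The 2 sets all but touched, at 9.436% in the highest wild-type library and 9.438% in the lowest variant library.

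At the left end of the domain, coverage of the ParB libraries stepped up at 4030555. It stayed on a plateau from 4030657 to 4030992 at 2.37 to 2.67 times background in the 8 ParB libraries, where YFP had 1.16. The 1 kb to the left of the step had 1.02 to 1.15 in the ParB libraries and 1.04 in YFP. The plateau lies above the limit of 2 times background, so it enters the left end of the domain. The adjoining block from 4031044 to 4031392 had 4.14 to 8.88 in the ParB libraries and 2.07 in YFP. Between the step and the plateau, at 4030635, coverage was 51.9% and 45.6% of the mean over 5 reference bases of the plateau in the 3K libraries, 71.7% and 58.0% in 4K and 44.1% and 82.0% in 5K, against 87.1% and 94.0% in wild type and 113% in YFP. This base was picked as the one where the variants were lowest against wild type, so that difference is built in. The 2 libraries labelled 5K differed from each other there by more than counting error (Fisher's exact test, p = 0.000845, adjusted p = 0.00338 over the 4 pairs of replicates). That test leaves out the spread between replicates, which was wider than counting error in each pair and widest in the 5K pair. For the other 3 pairs Fisher's exact test gave p = 0.239 to 0.777. These windows were chosen after the profiles had been seen. In the group means the left ends of the domain in wild type and variants differed by the 500 bp from 4030424 to 4030924. This stretch holds the step, the dip and part of the plateau, and the plateau averaged 2.52 in wild type and in the variants. The left part of the width difference therefore cannot be read as occupancy alone. On the right the width was 6 kb in both wild-type libraries and 4.5 or 5 kb in the variant libraries.

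**Figure D2:**
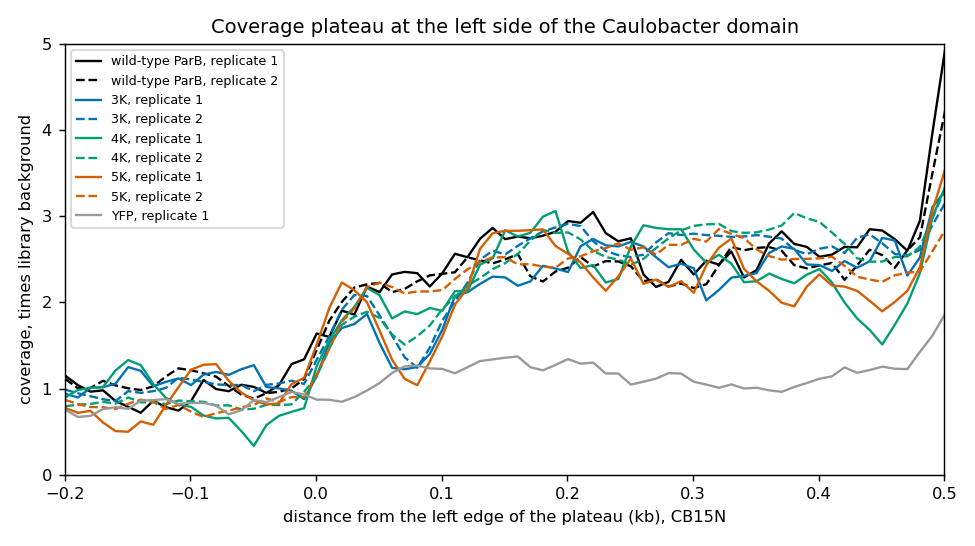
Fold over background against position around the coverage step at 4030555 in C. crescentus, 1 line per library. The 8 ParB libraries share a level of 2.37 to 2.67 from 4030657 to 4030992, YFP stays at 1.16, and the variant libraries dip at 4030635 to different depths.

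Across the chromosome, wild-type ParB was set against YFP in 1-kb bins. YFP has 1 library and was assumed to vary like the other groups, so these p-values rest on a spread taken from them. Of the 4017 bins tested with limma, 6 were higher in wild type and none was lower. They covered 4030001 to 4033000, with a log2 fold change of 3.30 ± 0.53 (SE) and folds of 13.7 and 1.29, and 4038001 to 4041000, with 3.33 ± 0.51 and folds of 12.1 and 1.11 (limma adjusted p = 0.0372 for both). Each value is that of the bin with the largest change. The first region includes the plateau, and the bins between the regions, with the centre, did not pass, with folds of 38.5 and 1.15 from 4035001 (log2 fold change 4.94 ± 1.28, limma adjusted p = 0.407). No bin passed in any of the 6 comparisons among the ParB groups, where limma gave unadjusted p under 0.05 for 217 bins in 3K against wild type, 303 in 4K against wild type and 225 in 5K against wild type. Between variants those counts were 34 for 4K against 3K, 35 for 5K against 3K and 17 for 5K against 4K. Without the 3 deep libraries limma called 3 bins in 4K and 1 in 5K against wild type, 6 in 4K and 2 in 5K against 3K, and 29 between wild type and YFP. In that fit 3K, 4K, 5K and YFP have 1 library each and are assumed to vary like the wild-type pair, which alone gives the spread.

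With the replicate number as a block in limma, 4 bins passed in 3K against wild type, all lower in 3K and 3 of them within 20 kb of the centre. In 4K against wild type 22 passed, 8 higher and 14 lower, and in 5K against wild type 9 passed, 1 higher and 8 lower, with 5 lower bins within 20 kb of the centre in each. With the block, 209 bins passed between wild type and YFP, 170 higher and 39 lower, and most lay beyond 20 kb of the centre, 158 higher and 38 lower. The 6 bins of that comparison depended on single libraries: limma called 0 bins without either wild-type replicate or either 4K replicate, and 12 without either 5K replicate, and without 3K replicate 2 the bin from 4032001 had a limma adjusted p of 0.0614. With a pseudocount of 0.5, or with no filter on low bins, limma called 0. Quantile normalisation gave 13 higher and 12 lower bins, 52% higher against 100%, of which 4 higher and 10 lower lay beyond 20 kb of the centre.

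The second comparison asked how the ParB proteins of 10 species spread around the same parS site in the same host. Coordinates are those of the E. coli K-12 MG1655 reference (ASM584v2), where the mean profile of the 18 libraries peaked at 2903137 inside ygcE (2901896 to 2903374). Each ParB had 1 library, so there is no replicate check and no test. Moorella thermoacetica ParB had the highest core fold, 139, and the highest flank fold, 82.1. Its domain of 53 kb ran from ygbI, 42.5 kb to the left, to relA, the gene of a ppGpp synthetase, 10.5 kb to the right. The lowest values were those of Xanthomonas campestris ParB, with a core fold of 9.31, a flank fold of 1.68 and a domain of 4.5 kb from yqcE to queE, a gene of queuosine synthesis. The highest values exceeded the lowest 14.9 times for the core, 48.9 times for the flank and 11.8 times for the width.

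Thermus thermophilus ParB occupied 38 kb, from cysC and cysN, genes of sulfate activation, to the mazE and relA genes, with a core fold of 27.9 and a flank fold of 8.79. Myxococcus xanthus ParB occupied 24 kb, from cysH, a sulfate assimilation reductase gene, to mazE and relA, with a core fold of 69.1 and a flank fold of 13.5. Domains of 13 and 12.5 kb that began in ygcN were measured for Lawsonia intracellularis and Bacillus subtilis ParB, with flank folds of 4.51 and 3.63. Those of Dechloromonas aromatica and Pseudomonas aeruginosa ParB began in ygcQ and measured 10.5 and 10 kb, with flank folds of 2.85 and 3.46. C. crescentus ParB reached from ygcU to yqcG over 7.5 kb and Helicobacter pylori ParB from ygcU to queE over 7 kb, with core folds of 22.2 and 13.7 and flank folds of 2.70 and 2.19. Right of queE, yqcG had a median fold of 0.487 over the 18 E. coli libraries, with 10 at 0.5 or less. The next gene, ygcG, was at 2 or more in 7, but eno beyond it in 11. The width rule can end a side at such a low stretch, so right ends at queE or yqcG may understate the reach. The order by core and by spread differed: P. aeruginosa ParB had a core fold of 38.3 and a distal share of 49.4%, the lowest of the 10, whereas T. thermophilus ParB had 27.9 and 79.1%, and M. thermoacetica ParB had 86.1%. In all 10 libraries the left flank exceeded the right, by 121 to 43.2 for M. thermoacetica and by 14.3 to 12.8 for M. xanthus. Reads within 20 kb of the centre made up 30.4% of all reads for M. thermoacetica (95% exact binomial interval 30.3 to 30.4), 7.39% for M. xanthus (7.36 to 7.42), 4.71% for T. thermophilus (4.69 to 4.73) and 1.28% for X. campestris (1.27 to 1.29), against 0.862% for even coverage.

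**Figure D3:**
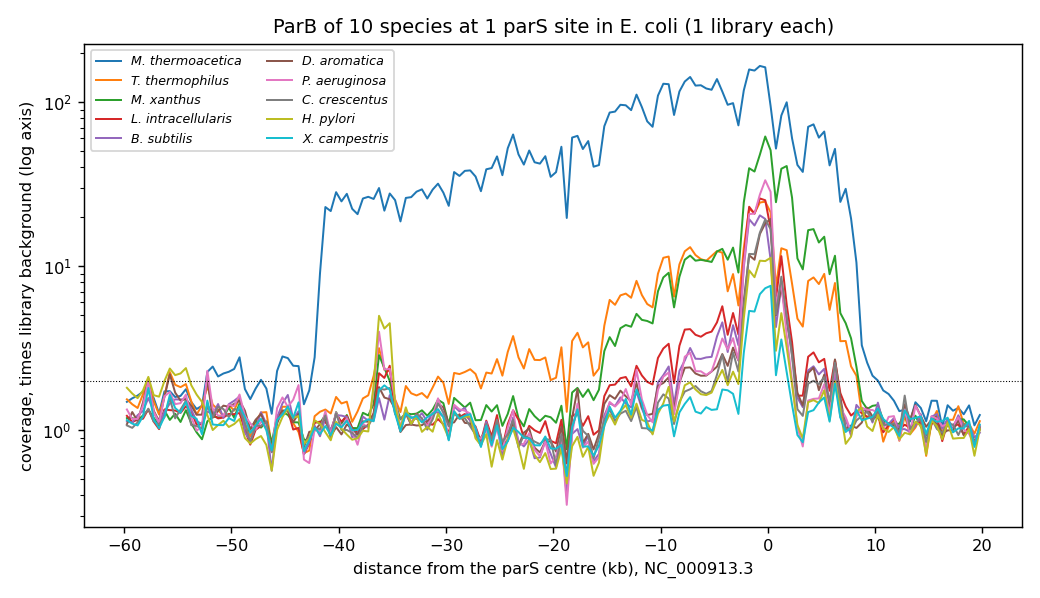
Fold over background (log axis) against position around the parS site inserted at ygcE in E. coli in 500-bp bins, 1 line for each of the 10 ParB libraries, with a dotted line at 2 times background. M. thermoacetica ParB stays above the line over 53 kb and X. campestris ParB over 4.5 kb.

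The third comparison asked how the 4 ParB chimeras differed at that site. Chimeras B and D spread over the region from ygbI and ygbJ to mazE and relA, while the contiguous domain ran from ygcU to yqcG in A and from ygcW to queE in C. The domain measured 50.8 ± 0.354 kb for B and 50.5 kb in both D libraries, against 7.5 kb in both A libraries and 5.75 ± 0.354 kb for C (SD, n = 2 each). The flank fold was 28.4 ± 1.76 for B and 31.4 ± 3.76 for D, against 2.76 ± 0.0953 for A and 2.16 ± 0.0973 for C. The core fold was 44.6 ± 2.16 for B and 50.4 ± 4.32 for D, against 20.1 ± 0.695 for A and 22.9 ± 1.71 for C. The distal share was 86.4% ± 0.261 for B, 86.0% ± 0.606 for D, 55.3% ± 0.232 for A and 44.3% ± 0.124 for C. Reads within 20 kb of the centre made up 14.9% and 13.9% of the B libraries and 15.8% and 14.1% of the D libraries, but 2.09% and 2.05% of A and 1.85% and 1.81% of C. The single library of C. crescentus ParB had a width of 7.5 kb, and that of M. thermoacetica ParB had a width of 53 kb.

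The exact permutation test over the 4 chimeras gave p = 0.00952 for the core fold, the smallest that the design allows, 0.0190 for the flank fold, 0.0190 for the distal share and 0.0286 for the domain width. After Benjamini-Hochberg adjustment over the 8 exact tests these were 0.0508, 0.0508, 0.0508 and 0.0571, so none passed 0.05 after correction. Single pairs of chimeras are given as values, since 2 libraries against 2 cannot give an exact permutation p below 0.333.

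**Figure D4:**
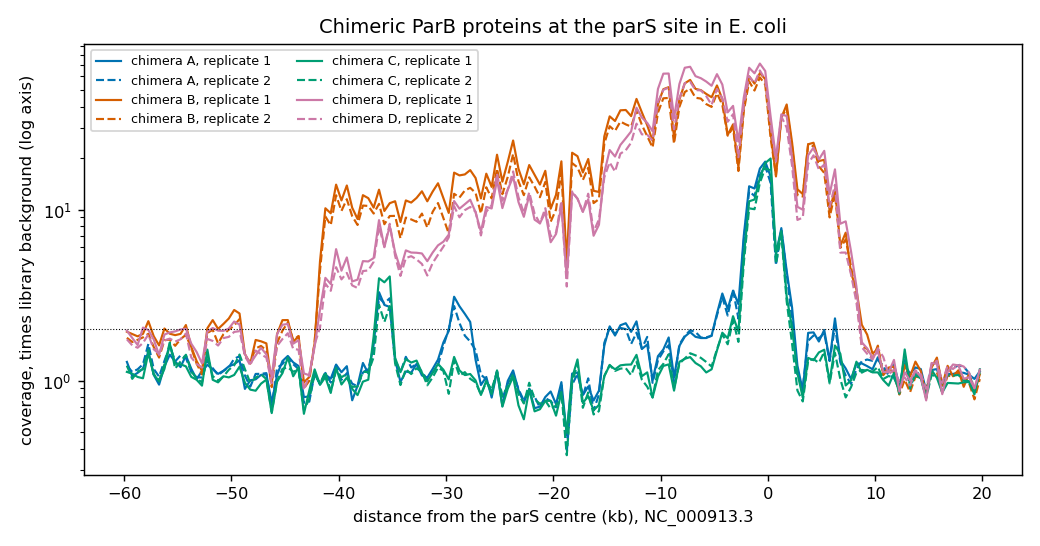
Fold over background (log axis) against position around the parS site inserted at ygcE in E. coli in 500-bp bins, 1 line for each of the 8 chimera libraries, with a dotted line at 2 times background. The B and D libraries stay above the line over 50.5 to 50.8 kb on average, the A libraries over 7.5 kb and the C libraries over 5.75 kb.

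In 1-kb bins around the inserted site, chimeras B and D exceeded A and C over the sulfite reductase genes cysI and cysJ and the ygc genes to the centre. The values given for a region are those of its bin with the largest change, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 4531 bins. From 2890001 to 2899000 (cysI to ygcU) the fold was 48.0 in B and 1.57 in A, a log2 fold change of 4.85 ± 0.16 (SE, adjusted p = 4.23e-10). From 2890001 to 2900000 (cysI to ygcW) D had 56.5 against 1.57 in A and 1.27 in C, log2 fold changes of 5.08 ± 0.16 and 5.36 ± 0.16. Over the CRISPR genes cas1 and casE (2879001 to 2880000) B had 19.9 and A had 1.01, a log2 fold change of 4.16 ± 0.12. Of the 40 bins within 20 kb of the centre, 30 rose and 1 fell in B against A, 29 rose in D against A, and 32 rose in D against C. Chimera D was lower than B toward the left end: over ygbK to ygbM (2863001 to 2865000) the fold was 4.65 in D and 12.2 in B, a log2 fold change of -1.37 ± 0.12 (adjusted p = 2.81e-05), and 8 bins within 20 kb fell. In C against A, 12 bins within 20 kb fell, and the ygbE, cysC and cysN bin (2873001 to 2875000) had 1.11 in C and 2.41 in A (log2 fold change -1.05 ± 0.14).

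Chimera A was higher than the other 3 around slyD and around htpG, far from parS. Around slyD, a peptidyl-prolyl isomerase, and the potassium efflux genes kefB and kefG (3478001 to 3481000), A had a fold of 4.96, B 1.53, C 1.71 and D 1.37. The log2 fold changes against A were -1.63 ± 0.10 for B, -1.48 ± 0.10 for C and -1.78 ± 0.10 for D, in regions that reached 3476001 to 3482000 for D. Around htpG, the gene of the Hsp90 chaperone (495001 to 497000), A had 2.74, B 1.15, C 1.27 and D 1.04, with log2 fold changes of -1.19 ± 0.07, -1.06 ± 0.07 and -1.32 ± 0.07. The sulfate transport genes cysW, cysU and cysP (2541001 to 2543000) had 1.24 in C and 2.88 in A, a log2 fold change of -1.15 ± 0.09. At ahpC, an alkyl hydroperoxide reductase gene, C had 2.83 and A had 6.15 (log2 fold change -1.06 ± 0.25, adjusted p = 0.0141). At the argZ to serV tRNA genes beside csrA, a carbon storage regulator gene, C had 1.53 and A had 3.19 (adjusted p = 0.00706). C exceeded A by smaller amounts at the lactaldehyde dehydrogenase gene aldA (0.86 ± 0.18), the purine repressor gene purR (0.66 ± 0.07), the arginine catabolism genes astA and astC (0.63 ± 0.14), the D-amino acid dehydrogenase gene dadA (0.62 ± 0.13), the chemoreceptor gene trg (0.63 ± 0.13), the peptide transporter gene dtpA (0.60 ± 0.17) and the diguanylate cyclase gene dgcZ (0.57 ± 0.07). Without A replicate 1 the limma adjusted p in C against A was 0.156 at ahpC, 0.0784 at the argZ cluster, 0.0918 at aldA, 0.0659 at astA and astC, 0.0859 at dadA, 0.0795 at trg and 0.19 at dtpA, all above 0.05. At dtpA it was also 0.0571 without A replicate 2, 0.13 without C replicate 1 and 0.0702 with no filter. The 2 C libraries lay far apart at aldA and dadA, and the SE rests on a spread shared over the groups. Over 1488001 to 1490000 at aldA C had 2.14 ± 0.80 and A 1.27 ± 0.08 (SD, n = 2 each), with 2.71 in C replicate 1. Over 1238001 to 1239000 at dadA C had 2.18 ± 0.60 and A 1.35 ± 0.03, with 2.60 in C replicate 1. The named bins where C exceeded A lay between 1237001 and 1832000. Coverage along the chromosome also differed between these chimeras. Lists matched on position to the origin-proximal genes had medians of 1.45 and 1.32 in A and 1.24 and 1.26 in C. Those matched to the segregation genes had 0.933 and 0.967 in A and 0.992 and 0.9999 in C. The fit held no term for position, so such a difference was not separated from one at single genes.

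Chimera B was lower than the other 3 at glpD, tnaA and aldA. At glpD, a glycerol-3-phosphate dehydrogenase gene, B had a fold of 1.69, against 4.22 in A, 4.08 in C and 3.58 in D, with log2 fold changes of -1.28 ± 0.16 for B against A and 1.05 ± 0.16 for D against B. At tnaA, the tryptophanase gene, B had 0.871 and A had 2.29, C 2.11 and D 1.94. The C libraries lay far apart at both genes. At glpD C had 4.08 ± 1.16 (SD, n = 2), with 4.90 in replicate 1. Over 3889001 to 3891000 at tnaA C had 2.66 ± 0.92, with 3.31 in replicate 1. At aldA the log2 fold change was -1.23 ± 0.18 in B against A, 1.80 ± 0.18 in C against B and 1.00 ± 0.18 in D against B. At putP, a proline transporter gene, it was -1.16 ± 0.08 in B against A and 1.01 ± 0.08 in D against B. C also exceeded B at dadA (1.29 ± 0.13), at the glycerol uptake genes glpK and glpF (1.15 ± 0.16) and at the glucose transporter gene ptsG (1.11 ± 0.12). D exceeded B at the nucleoside channel gene tsx (0.99 ± 0.16) and the glycolate genes glcA and glcB (0.95 ± 0.07), glcE to glcG (0.97 ± 0.09) and glcD (0.91 ± 0.26). At glcD the limma adjusted p was 0.0995 without B replicate 1, 0.053 without B replicate 2, 0.148 without D replicate 1, 0.0639 without D replicate 2, 0.0834 with no filter and 0.251 with quantile normalisation. B was higher than D at ribosomal RNA and tRNA genes: the log2 fold change of D against B was -2.12 ± 0.14 at rrsH, -1.72 ± 0.29 at rrlC to trpT, -1.55 ± 0.21 at rrlH, -1.48 ± 0.28 at rrlA, -1.44 ± 0.08 at valZ to lysQ, -1.35 ± 0.17 at argX to proM and -1.31 ± 0.07 at the glnX cluster. Without B replicate 2 the limma adjusted p at rrlA was 0.05, and with quantile normalisation that at argX to proM was 0.23. Several of these genes have near-identical copies, among which reads cannot be placed with certainty, so their values are uncertain. D was lower than C at aldA (folds of 0.756 and 1.68), purR (-0.89 ± 0.07), dtpA (-0.79 ± 0.17), dadA (-0.78 ± 0.13), the topoisomerase gene topA (-0.77 ± 0.09), ybjX (-0.76 ± 0.08), trg (-0.76 ± 0.13), dgcZ (-0.75 ± 0.07) and the oligopeptide transport gene oppA (-0.74 ± 0.18). Without D replicate 1 the limma adjusted p was 0.072 at oppA and 0.0535 at dtpA. At aldA and dadA the C libraries lay far apart, as given above. The named bins where D was lower than C lay between 919001 and 1739000.

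Over all bins limma called 2435 between B and A (1121 higher and 1314 lower in B), 2202 between C and B (1150 higher and 1052 lower in C), 1569 between D and C (680 higher and 889 lower in D), 1456 between D and B (633 higher and 823 lower in D), 1333 between C and A (758 higher and 575 lower in C) and 432 between D and A (387 higher and 45 lower in D). Single libraries moved several counts. In B against A the lower bins fell to 662 without A replicate 1, 742 without B replicate 1 and 824 without B replicate 2, so that 59.8%, 57.6% and 54.9% were higher against 46.0%. In D against B 27.4 to 30.9% were higher when any single B or D replicate was left out, against 43.5%, and in C against A 67.2% without C replicate 2. C against A fell to 136 without A replicate 1 and to 580 without C replicate 1, and D against A to 167 without A replicate 1 and to 150 without D replicate 1. D against B fell to 796, 842 and 677 without B replicate 1, D replicate 1 and D replicate 2, and D against C to 1031 and 919 without C replicate 1 and D replicate 1. Scaling by the mean instead of the median background gave 914 higher and 274 lower bins in C against A, 76.9% higher against 56.9%, and quantile normalisation called 591 bins in all there. Bins of 500 bp gave 577 kb. Position along the chromosome was not a term in any of these fits. The counts therefore include any difference between chimeras in how coverage varied along the chromosome.

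Away from parS, bins of 500 bp beyond 50 kb of the centre at 3 times background or more, where the panel median was below 1.5, were most numerous for T. thermophilus ParB, with 83 in 28 regions and 41.5 kb. None of the 18 E. coli libraries is a control without ParB. Bins left out because the panel median was 1.5 or more numbered 118 for C. crescentus, 111 for P. aeruginosa, 103 for H. pylori, 98 for D. aromatica and 93 for T. thermophilus ParB. At 2 times background P. aeruginosa ParB had more regions than T. thermophilus ParB, 77 against 58, though fewer bins, 89 against 184. For T. thermophilus ParB the region from gstA, a glutathione transferase gene, to ydhJ (1714501 to 1722000) had a mean fold of 7.36. No other library exceeded 0.989 there. In the same T. thermophilus library the region from ybiU to ybiY (859001 to 863500) had 7.24. That from hdeD to mdtF (3657001 to 3661500), which holds the acid resistance regulator gene gadE, had 8.43 in it. The region dnaX to fsr (494001 to 504500), with htpG, had 3.77 in it. These regions were joined across gaps of up to 2 kb, a step chosen after seeing the data. H. pylori ParB had 19 such bins in 12 regions, led by the region from tusC to slyD (3475001 to 3478000, mean fold 4.49) and that at kefG and yheS (3481001 to 3482500, 4.97). C. crescentus and D. aromatica ParB had 6 bins each, among them the pyruvate formate-lyase gene pflB with the formate channel gene focA (952501 to 954000, 4.98) for C. crescentus and yibU to yibI (3770001 to 3771500, 4.75) for D. aromatica. The pflB site was shared: D. aromatica ParB also had bins there (952001 to 953500, 3.68). P. aeruginosa ParB had 7 bins, led by glcD (3127501 to 3128000, 3.75). Chimeras A and D had 2 each in both replicates, B. subtilis ParB had 1 at lacI (366501 to 367000), which overlaps a block at lacZ and lacI (366302 to 366522) that was high in all 18 libraries, and M. thermoacetica ParB had 1 at tsx. L. intracellularis, M. xanthus and X. campestris ParB and chimeras B and C had 0, in a count that involves no test. In C. crescentus the only such bin was the remote site in wild type, 3764001 to 3764500, with a fold of 3.82, where the highest variant library had 3.39.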

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

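No group holds 4 or more libraries, no contrast is shared by 2 groups, and each of the 27 libraries entered a comparison, so no result is set apart here.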

How the results depend on the processing

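The thinned reads, the 3 deep libraries left out, the shallow libraries and the block for wild type against the variants were alternatives chosen after seeing the data. None of the named bins changed sign, and the signs of the other bins were not compared across alternatives. The balance of bins in B against A turned from more lower to more higher without A replicate 1, B replicate 1 or B replicate 2. Of the values of the main results, 315 stayed on their side of the threshold or close to their value, 26 became weaker, 15 stronger and 3 moved, and of the 59 named bins under 828 alternatives 795 stayed called and 33 did not. Among single values with no test, 235 moved by more than the spread and 224 did not.

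For C. crescentus, thinning to the read number of the shallowest library brought the width test to exact permutation p = 0.0286, and to 0.0833 with the block as well. Limma without the 3 deep libraries called 3 bins in 4K and 1 in 5K against wild type, 6 in 4K and 2 in 5K against 3K, and 29 between wild type and YFP, with 1 library each of 3K, 4K, 5K and YFP assumed to vary like the wild-type pair. With no filter it called 1 bin in 4K against wild type and 0 between wild type and YFP, where a pseudocount of 0.5 gave 0 and quantile normalisation 25, and leaving out single replicates gave 0 to 12. Wild type against the shallow variant libraries gave exact permutation p = 0.1 for core fold, flank fold and width, because 5 libraries allow no smaller p. In the other cases the cause was not tested.

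With the replicate number as a block, limma called 4, 22 and 9 bins in 3K, 4K and 5K against wild type and 209 between wild type and YFP. Wild type against the 6 variant libraries then gave exact permutation p = 0.0625, the smallest of 16 assignments, for core fold, flank fold and width, and so did the 7 tests of summits that had p = 0.0357 without the block. The block also took the exact permutation p of the width with thinned reads from 0.0286 to 0.0833. Where it was run, the pairing changed no other call of C. crescentus. The chimera numbers did not meet the rule for pairs, although 4 of the 6 correlations exceeded 0.1 and each second replicate was deeper, with a lower read share within 20 kb. There the block gave exact permutation p = 0.0833 for the width, also with thinned reads, and 0.0417, the smallest of its 24 splits, for the other 3 quantities, and limma counts of 2534, 1494, 458, 2308, 1608 and 1649 for B, C and D against A, C and D against B, and D against C.

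For the chimeras, C against A gave 577 kb in bins of 500 bp and 591 bins with quantile normalisation. Leaving out single replicates gave 136 to 1192 bins for C against A, 150 to 497 for D against A, 677 to 1662 for D against B and 919 to 1635 for D against C, with fewer samples in each fit and the lone library of a group assumed to vary like the other groups. The panel ratios of highest to lowest became 39.2 for the flank from 0.5 to 5 kb, and 9.92 and 14.6 for the width at 1.5 and 3 times background. The other peaks covered 286.5 kb in all at 2 times background and 18 kb at 5 times, as the threshold sets. Matches to the parS motif, with up to 2 or 3 mismatches, and the C. crescentus gene lists were not run. Single bases hold few reads in the shallow libraries of C. crescentus, for example 32 to 109 at 4030635 in those with ParB.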

Other observations

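The tests of wild type against the variants, of the plateau, of the shared left end and of position-matched lists were chosen after the result was seen, and the gene lists other than the prophage genes were set beforehand.

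In the 18 E. coli libraries, coverage was above background over ribosomal protein genes in all libraries and over tRNA genes in most. The 54 ribosomal protein genes had a median fold of 1.28 (chimera C replicate 2) to 2.85 (D. aromatica ParB), above all 10000 random lists of the same size in each of the 18 libraries, and also above all 10000 lists matched on position, in which each member was replaced by a gene within 200 kb. Among them rplN had a median over libraries of 3.37, rpsM 3.15 and rpmB 3.06. Neither kind of list was matched on gene length or kept neighbouring genes together. Many of the 54 genes lie side by side between rplQ (3439616) and rpsJ (3453270), and many tRNA genes lie in clusters. Neighbours can share coverage, so the percentiles of both lists can overstate the evidence. The 86 tRNA genes ran from 0.724 (chimera C replicate 2) to 4.53 (D. aromatica ParB), with 3.17 for C. crescentus ParB, 2.79 for P. aeruginosa ParB, and 2.47 and 2.34 in the chimera B libraries. They lay above the central 95% of random lists in 11 libraries and below it in 4, and above that of position-matched lists in 11 and below it in 6. The genes serV, hisR, argX and cysT had medians over libraries of 10.3, 9.23, 8.05 and 6.80, and in all 18 libraries 9 of the 86 were at 2 times background or more and 11 at 0.5 or less. Of those 11, ileV, alaU, ileU, alaT and thrW had 0 in every library, and thrW (262871 to 262946) lies in a stretch almost without coverage from gpt to insH1. Such values cannot be read as low occupancy. The 22 rRNA genes, which have near-identical copies, had medians of 0.0505 to 0.517, and rrlG, rrlB and rrfH had 0 in every library. Reads were thus not divided evenly among the copies, so these low values cannot be read as low occupancy. The 6 origin-proximal genes, among them the replication initiator gene dnaA, had 1.37 to 2.11 and lay at percentiles of 98.7 to 100, but among position-matched lists at 87.2 to 98.6, above the central 95% in only 4 libraries. The 8 segregation genes, among them mukB and the Ter macrodomain gene matP, had 0.952 to 1.16, and none of them was at 2 or more or at 0.5 or less in any library. The 4 lac genes, listed as loci that the expression plasmid can share with the chromosome, had medians of 1.05 to 3.02. Of the 20 neighbours of the inserted site, with medians of 1.19 to 92.5, ygcE, yqcE and queE were at 2 times background or more in all 18 libraries.

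Stretches of at least 5 kb were almost without coverage in all 18 E. coli libraries, 3 stretches and 48 kb in all. They ran from gpt to insH1 (256001 to 275000), which holds the proline synthesis genes proA and proB, from intR to ttcC (1412001 to 1435000) in the Rac prophage and from intZ to yffS (2559001 to 2565000). The highest library had 0.0111, 0.0138 and 0 times background in them. The proA, proB and gpt genes had a median of 0 in each library, and so had the 21 Rac genes found of 24 names looked up, members chosen after seeing the data. At ahpC, picked out after its values were seen, folds ran from 2.45 to 16.1 (C. crescentus ParB), with 13.3 for D. aromatica ParB and a median of 6.84. The slyD to kefG site that marked chimera A had 7.71 in H. pylori, 5.39 in T. thermophilus and 3.69 in L. intracellularis ParB, against a median of 1.67, and at htpG T. thermophilus ParB had 3.68 and H. pylori ParB 2.81.

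In E. coli, a block of coverage at the junction of lacZ and lacI (366302 to 366522), picked out after its values were seen, stood, over its inner part from 366353 to 366471, at 13.4 times background in the lowest library (X. campestris ParB), 175 in the highest (B. subtilis ParB) and 19.3 in the median of 18, while the neighbouring sequence had 0.814 to 2.87 on the left and 0.741 to 3.18 on the right. All of these libraries came from cells with plasmid pUT18C. The lac genes had been listed beforehand as loci that the expression plasmid can share with the chromosome. Whether reads from the plasmid make up the block was not tested, so it cannot be read as ParB occupancy.

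Wild-type ParB lay above the 6 variant libraries at the C. crescentus centre. Library depth as the only cause is argued against by the shallow libraries alone, where the wild-type mean core fold was still 1.95 times that of the variants with no overlap. The exact permutation p there was 0.1, the smallest that these libraries allow. A part played by depth stays open, since the ratio over all libraries was 2.48. The deep library had the lower core fold in each variant, 20.7 against 22.6 in 3K, 17.1 against 31.7 in 4K and 11.6 against 31.9 in 5K. A uniform drop in pull-down efficiency stays open. At 2 of the 4 side summits the variants stood lower against the centre (44.9% against 62.3% and 43.9% against 63.9%), but with an adjusted p of 0.0893, and 0.0625 with the block, which cannot go lower (exact permutation). The other 2 overlapped. Of these, the summit at 4031346, with the smallest difference of 2.54 points, lies in a block raised in YFP too, so it cannot decide. The distal share gave an exact permutation p of 0.821, and the remote site at 3764141 went the other way (8.40% in wild type against 14.0% in the variants, exact permutation p = 0.0714). Whether the variant carried is the cause stays open (exact permutation p = 0.0357 for 2 against 6 libraries, but 0.0625 with the replicate block, which cannot go lower). A lower amount of FLAG-tagged protein in the variants stays open too and was not tested.

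In C. crescentus, a plateau lay at the left end of the domain, within the flank window: coverage from 4030657 to 4030992 was at least 2.37 times background in each of the 8 ParB libraries and 1.16 in YFP, with a dip just left of it, at 4030635. The plateau varied only 1.13 times between the highest and lowest ParB library while their core folds varied 5.79 times. An additional copy of this sequence in the ParB strains would give such a level, whereas occupancy would vary with the core. By their labels these strains carry a gene for FLAG-tagged ParB at vanA, where the YFP strain carries one for YFP. The adjoining block from 4031044 to 4031392 stood at 2.07 in YFP too, with 4.14 to 8.88 in the ParB libraries. No annotation of CB15N was used, so whether these windows hold parB, and which sequence was copied in which strain, stays open. The base of the dip was picked because the variants were lowest there against wild type, so the upper bounds of the 3K libraries (71.7% and 52.6% of 5 reference bases of the plateau, against 87.1% or more in wild type) do not decide whether sequence changes in the 3K copy keep reads from aligning. The difference between the 2 libraries labelled 5K there (Fisher's exact test, adjusted p = 0.00338) covers counting error only, so different inserted sequences in them stay open, while a wild-type culture in replicate 2 is argued against by its core fold of 11.6, below both wild-type libraries (67.0 and 45.1). What was inserted in each strain was not tested beyond this, and other strain differences stay open.

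In M. thermoacetica ParB and in chimeras B and D, coverage fell on the left at nearly the same place, between ygbI and ygbJ in 4 of the 5 libraries taken singly (2861386 to 2861413) and inside ygbI in chimera D replicate 1 (2861170), although M. thermoacetica ParB still had a fold of 2.65 in the 1 kb outside 2861396 and its domain by the width rule reaches further. Missing or unmappable sequence there is argued against by the other 13 libraries, whose coverage in the 1 kb inside 2861396 was at most 1.252 times that in the 1 kb outside. An effect of the threshold of 2 times background alone is argued against by the step itself, which was 2.36 to 7.83 times in the 5 libraries at the place found without their own group. On the right, at 2911366 inside ameF, the step was 2.23 to 5.54 times in the 5 libraries and 0.713 to 2.48 in the others. The highest of the others were M. xanthus ParB (2.48) and T. thermophilus ParB (1.88), whose domains also ended at mazE and relA. The next was L. intracellularis ParB at 1.05. A barrier to spreading at these places, or a feature of the chromosome of this strain, was not tested and stays open.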
